A study of Drosophila melanogaster with 3 samples.

How the data were processed

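Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out with an anti-GFP antibody on whole Drosophila melanogaster embryos of 8 to 24 hours that carried gce fused to eGFP. The labels give 3 biological replicates of this 1 group, sonicated chromatin and a fragment size range of 200 to 800 bp. The replicate numbers are those in the labels. A control experiment is named in the labels and was not analysed here, so no background from a control sample stands beside the values. The series holds no second condition, and the comparisons made are between replicates, between peaks and shuffled positions, between gene lists and other genes, and between summits and nearby sequence.

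The deposited files are peak lists on the dm6 assembly, per the labels. For each replicate there is a ranked list and a list thresholded on the irreproducible discovery rate (IDR), which measures how well the ranks of peaks repeat between 2 sets of calls. Per the deposited text beside the lists, both kinds were derived from a control file and the filtered alignments, and the thresholded lists have 1 further input that the ranked lists do not have. The peak caller, the aligner and their versions are not given in the sources used here. The deposited score of each peak is a rescaled IDR with a highest value of 1000, and the lowest score in the thresholded lists, 830, corresponds to an IDR of 0.01. The deposited signal value of each peak is the authors' own, its scale is not stated, and it was used only to rank or filter peaks within 1 list. The summit offset from the start of each peak was also taken from the deposited lists, and a further deposited score for the false discovery rate was used only to break ties in rank.

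The series also has 4 thresholded lists made from the alignments of all 3 replicates. The text beside them does not say which pair or pool each one compared. The list named conservative, with 2379 peaks, was the main list, and the lists of 1745, 2133 and 3770 peaks served as alternatives. The ranked lists of the whole series were not used. Of the conservative peaks, 2376 lie on X, 2L, 2R, 3L, 3R, 4 or Y, and the 3 others were left out. Read depth cannot be seen in peak lists, so the precision of each value is set by the number of peaks and replicates, and intervals cover counting error only. Exact binomial (Clopper-Pearson) intervals are at the 95% level.

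Genes and transcription start sites (TSSs) were taken from Ensembl release 115 for the same genome release as dm6, with 13968 protein-coding genes and 19275 of their TSSs on the arms. No peak lies beyond the end of its chromosome in the reference sequence. The annotation copy may differ from any the authors used. A summit within 500 bp of a protein-coding TSS was classed as promoter, and the others as 5′ UTR, CDS, 3′ UTR, intron or intergenic in that order. A gene counted as bound when a summit lay within 1 kb of any of its TSSs, which says where the summit is and not which gene it acts on. Peaks were called shared when they overlapped by at least 1 bp.

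Before the data were examined, 27 gene lists, 20 sequence words (3 of them control words), the tests and most alternatives were fixed. Of 326 symbols written out in the lists, 11 were matched through synonyms. Locations and replicate sharing were tested against 1000 shuffles of positions within each arm, two-sided for locations and one-sided for sharing, so that the smallest p is 0.0020 and 0.0010. Each gene list was tested with Fisher's exact test, two-sided, against all other protein-coding genes (all annotated genes for tRNA genes), and each word with an exact McNemar test, two-sided, of its presence within 100 bp of the summit against a window of the same 201 bp centred 500 bp away on a random side. Benjamini-Hochberg adjustment was made over the 27 lists, over the 20 words and over the location classes, with a threshold of 0.05. Peak numbers per arm were tested with a permutation test of 100000 multinomial draws against the number of protein-coding genes. Neighbouring genes and peaks are not independent replicates, so these p-values describe the peak list.

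The rule for named genes, also fixed beforehand, takes every member of the juvenile hormone list, the gene with the nearest TSS within 5 kb of each of the 25 peaks with the highest signal, and up to 4 bound members of every other list of protein-coding genes by signal. Alternatives covered the other series lists, stricter subsets, leaving out each replicate in turn, other overlap rules, other windows, lists matched on TSS number with 10000 draws, windows matched on GC content in bins of 5% and on distance class to a TSS (or on the latter alone, added after the data were seen), and arm length in place of gene number. The alternative of filtering at an IDR of 0.01 gave no further value, because the lists already start there. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

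The statistics were tested on simulated data with 2376 peaks. A planted list of 30 genes, 15 of them bound, was recovered in 10 of 10 runs, and 2 of 250 random lists were called. A word planted in 10% of summit windows was recovered in 10 of 10 runs, and 0 of 200 tests at random positions gave a call. CACGTG was at 2.95% of real summits, so recovery at 10% does not show that a small excess would be found. Random positions do not have the lower GC of real summits against their flanks (39.0% against 42.5%). The 0 of 200 therefore does not give the rate of false calls at real summits. The arm test called 0 of 10 random draws.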

Results

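The series measured where the Drosophila protein germ cell-expressed (gce), a bHLH-PAS transcription factor and juvenile hormone receptor related to Methoprene-tolerant (Met), lies on chromatin in embryos of 8 to 24 hours. Positions are on the dm6 assembly. All 3 samples are biological replicates of 1 group of whole transgenic embryos with eGFP-tagged gce, immunoprecipitated with an anti-GFP antibody. Replicate 1 had 1112 peaks past the IDR threshold, replicate 2 had 1604 and replicate 3 had 1882, a mean of 1533 ± 390 (SD, n = 3). These covered 0.204%, 0.314% and 0.355% of the arms. The ranked lists before thresholding held 90027, 102616 and 90425 peaks.

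Most of the strongest peaks passed the IDR threshold in every replicate and few of the weaker ones did. Of the 500 conservative peaks with the highest signal, 91.4% overlapped a peak in all 3 replicates, against 39.8% of the next 500 and 1.60% of the remaining 1376. Over the whole conservative list 678 of 2376 peaks (28.5%, interval 26.7 to 30.4) were found in all 3, and 525 in none of them. The conservative list was made from the alignments of the same replicates, so overlap above the mean of 0.243% at shuffled positions was built in. The shares are also bounded by list length, as replicate 1 has 1104 peaks on the arms, which meet 954 conservative peaks, and a peak not counted can still be present below the threshold. Between pairs of replicates the share of one list found in the other ran from 46.6% (replicate 3 in replicate 1) to 79.0% (replicate 1 in replicate 3), with a mean of 57.8%. For each of the 6 ordered pairs the share was above shuffled positions (at most 1.81%, one-sided permutation p = 0.0010, the smallest it can give). The 1104 peaks of each replicate with the highest signal, set against the full list of each other replicate, gave a mean of 68.6%.

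**Figure D1:**
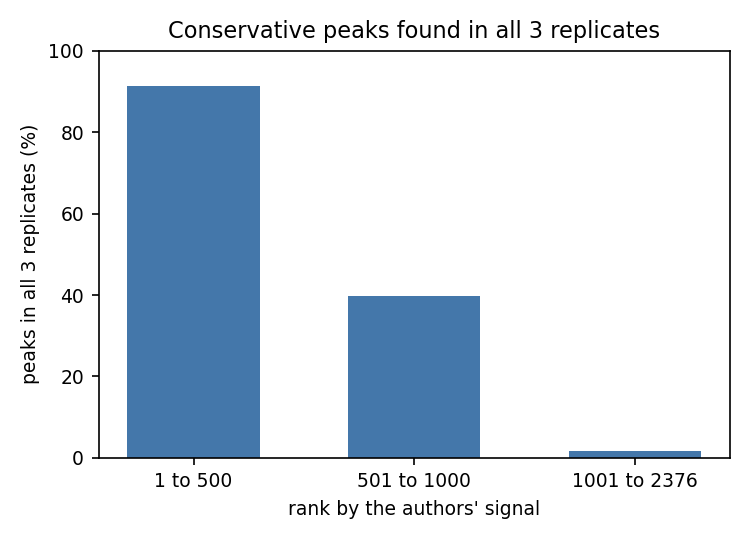
Share of conservative-list peaks (percent, vertical axis) that overlap a thresholded peak in all 3 replicates, in 3 ranges of rank by the authors' signal (horizontal axis). The bar falls from 91.4% for ranks 1 to 500 to 1.60% for the last 1376 peaks.

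Each of the 25 peaks with the highest signal was present in all 3 replicates, and 17 of them had their summit at a promoter. The peak of rank 1 lay 37 bp from a TSS of Ugalt (FBgn0024994, X:2701124-2703852), which encodes a UDP-galactose transporter, with its summit at X:2703889. Ranks 2 and 4 to 7 lay at promoters of CG14100, CG7601, Tcs5, mRpL41 and PNPase, each with a summit 85 to 126 bp from a TSS. Further promoter peaks in this group were at Art3, CenG1A, px, CG18549, CG5611, CG13390, Fkbp14, RluA-1, Elp5, Chro and CG1888. The summits nearest to ph-p (a Polycomb group gene), Tlk, CG11050 and CG32772 were intronic. Those nearest to CG31668, hll and tara were intergenic, 2924 to 3784 bp from a TSS. The peak of rank 8, on 2R at 13035233 to 13035439, had no protein-coding TSS within 5 kb. The 41 bp of reference sequence centred on the Ugalt summit, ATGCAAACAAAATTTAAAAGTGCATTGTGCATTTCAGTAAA (X:2703869-2703909), have a GC content of 26.8%.

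Promoters held 4.13 times as many summits as shuffled positions. Within 500 bp of a protein-coding TSS lay 47.6% of conservative summits (interval 45.6 to 49.6), against a shuffled mean of 11.5%. The replicates gave 45.6% ± 3.88 (SD, n = 3). Coding sequence was nearly free of summits, with 0.631% against 13.9% in shuffled positions, and 3′ UTRs held 0.758% against 4.46%. Intergenic positions (16.2% against 30.2%) and introns (34.3% against 39.2%) were also below the shuffled mean. For each of these 5 classes the two-sided permutation test gave adjusted p = 0.0024. The 5′ UTR share, 0.547% against 0.782%, did not pass the permutation test (adjusted p = 0.228). Ranked peaks that missed the IDR threshold had a promoter share of 13.7% ± 1.58 (SD, n = 3).

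**Figure D2:**
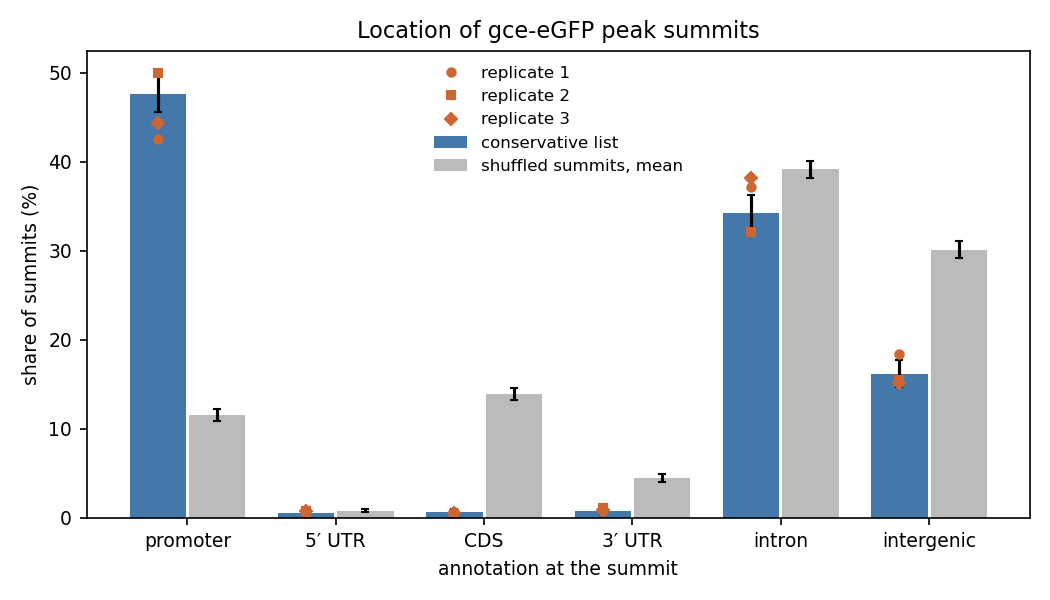
Share of summits (percent, vertical axis) in each annotation class (horizontal axis) for the conservative list with exact 95% intervals, for shuffled summits with mean and SD of 1000 shuffles, and for the 3 replicates as points. Promoters hold 47.6% of conservative summits and 11.5% of shuffled ones, and coding sequence 0.631% and 13.9%.

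Genes of the cytosolic ribosome were bound far more often than other genes. Of 92 cytosolic ribosomal protein genes, 60 (65.2%, interval 54.6 to 74.9) had a summit within 1 kb of a TSS, against 11.3% of other protein-coding genes (Fisher's exact test, adjusted p = 1.57e-32). The shares in replicates 1, 2 and 3 were 31.5%, 63.0% and 52.2%, against 5.41%, 8.05% and 9.29% of other genes. The peaks with the highest signal were at RpS27 (3R:25245955-25247514, summit 9 bp from a TSS), RpL7, RpL24 and RpL14, each found in all 3 replicates. The 41 bp around the RpS27 summit read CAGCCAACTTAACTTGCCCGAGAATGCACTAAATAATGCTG (3R:25247485-25247525). Mitochondrial ribosomal protein genes were not above background as a list, at 11 of 73 (15.1% against 11.7%, Fisher's exact test, adjusted p = 0.572), although mRpL41, mRpS10, mRpS23 and mRpL23 lay at peaks of rank 6, 9, 10 and 34. The peaks of rank 9 and 10 are shared with Art3 and CenG1A. Of the proteasome genes, 1 of 32 was bound (Rpt5, Fisher's exact test, adjusted p = 0.353). In total 1633 of the 13968 protein-coding genes (11.7%) were bound, and 562 were bound in all 3 replicates' own lists.

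A further 3 lists were above background with fewer genes. Of the nuclear receptor genes outside the ecdysone list, 6 of 12 were bound (50%, against 11.7% of other genes, Fisher's exact test, adjusted p = 0.0067), among them Hr51 and Hr96, whose peaks were found in all 3 replicates, and Hr78 and eg. Heat shock genes had 7 of 18 bound (38.9%, Fisher's exact test, adjusted p = 0.0131), with Hsp27 at rank 79 and Hsp83 at rank 99 in all 3 replicates, Hsp26 in 2 and Hsp22 in 0. The developmental signalling list had 10 of 34 bound (29.4%, Fisher's exact test, adjusted p = 0.0167), including the Wnt antagonist nkd in all 3 replicates, and the EGFR pathway genes pnt and rho and the Wnt receptor fz2 in 2, 1 and 2. In a permutation test with lists matched on TSS number, the calls of nuclear receptors (background 16.9%, adjusted p = 0.0537) and signalling (background 13.3%, adjusted p = 0.0802) were lost, with both shares still above the matched background, and that of heat shock genes held (background 12.2%, adjusted p = 0.0302). All 3 calls were also lost with only the peaks found in all 3 replicates or in any pair of them, sets with fewer peaks. In all 3 replicates the shares were 16.7% for nuclear receptors and 11.1% for heat shock genes, both still above 3.91% of other genes. Signalling was below background, at 2.94% against 4.08%, without replicate 3. That value counts only conservative peaks that overlap a peak in both other replicates. In each replicate's own list the signalling share was 20.6%. Other genes were at 5.5%, 8.4% and 9.5% in replicates 1, 2 and 3, and these differences were not tested. With each summit given to its nearest TSS the signalling share was 52.9% against 12.6% (Fisher's exact test, adjusted p = 1.87e-07). Of the 7 bound heat shock genes, 5 lie in a cluster of 7 list members on 3L (9371511 to 9385694). Among the other 11 members 2 were bound, Hsp83 and Hsc70-4 (18.2%, Fisher's exact test, unadjusted p = 0.374), a split made after the values were seen. The other members include the repeated Hsp70 genes, none of them bound, where reads may not be placed with certainty. The split therefore cannot show that the excess is confined to the cluster.

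The juvenile hormone list did not pass the test. Of its 17 genes 4 were bound (23.5%, interval 6.81 to 49.9, against 11.7% of other genes, Fisher's exact test, adjusted p = 0.316), namely gce, Jheh1, Hmgs and JhI-21. The gene gce (FBgn0261703, X:15297766-15319074) held an intronic peak of rank 70 in all 3 replicates, at X:15298336-15298490 with the summit 605 bp from a TSS, and the reference sequence around it was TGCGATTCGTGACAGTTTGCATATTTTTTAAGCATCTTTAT. The embryos are transgenic for gce-eGFP, and peak lists cannot show whether reads at the gce peak came from the endogenous gene. The peaks at Hmgs and JhI-21 overlapped none in the thresholded lists of the replicates and that at Jheh1, an epoxide hydrolase gene, was found in 1. The nearest summit to Kr-h1, an early juvenile hormone response gene, was 2905 bp from a TSS (2L:6088507, intronic, rank 846, in 2 replicates), with the sequence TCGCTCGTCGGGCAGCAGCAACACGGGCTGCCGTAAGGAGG. Nearest summits were 1727 bp away for tai, 4928 bp for Jhe, 4922 bp for JhI-26, 2742 bp for Jheh2, 6880 bp for Jheh3, 7953 bp for Jhedup, 6026 bp for RNaseZ (listed as JhI-1), 14633 bp for jhamt, 18298 bp for Fpps, 13071 bp for Met and 91871 bp for br. The distance of 1 further member is not used here. Within 5 kb of a TSS 10 of the 17 had a summit (58.8% against 24.6%, Fisher's exact test, adjusted p = 0.0107), with Jheh1 and Jheh2 sharing 1 peak. The summits near Jhe and JhI-26 lay at promoters of other genes, and the JhI-26 peak was in 0 replicates. The JhI-21 peak was also counted for RpL7-like. With each summit given to its nearest TSS the share was 35.3% against 12.7% (Fisher's exact test, adjusted p = 0.0361). No call was made in the other 12 alternatives, among them lists matched on TSS number (23.5% against 16.6%, permutation test, adjusted p = 0.875) and peaks in all 3 replicates (5.88% against 3.92%, Fisher's exact test, adjusted p = 0.833).

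A group of 3 lists lay below background. Among cuticle protein genes 1 of 122 was bound (Cpr73D, 0.820%, Fisher's exact test, adjusted p = 4.51e-05), among chemoreceptor genes 1 of 179 (Or88a, 0.559%, adjusted p = 1.52e-07), and among replication-dependent histone genes 0 of 111 (upper limit 3.27%, adjusted p = 1.56e-05). The histone genes are near-identical repeats, where reads cannot be placed with certainty, so their value is uncertain. The cuticle and chemoreceptor calls were each lost in 2 of 14 alternatives and the histone call in 3.

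The other lists gave no call. Bound genes numbered 5 of 27 for ecdysone (Eip63E, crol, Eip75B and usp, each in at most 1 replicate, and ftz-f1, named outside the rule after its values were seen), 1 of 14 for bHLH-PAS and clock genes (Pdp1, in 2 replicates), 2 of 23 for Hox and segmentation genes (en and Ubx) and 7 of 29 for insulin, TOR and metabolism (with InR at rank 138 and Thor at rank 617 in all 3 replicates, and bigmax and Sik3). Cell type markers were bound at 3 of 12 for neural progenitors (brat, insc and SoxN), 2 of 14 for neurons (elav in all 3 replicates, and fne), 2 of 9 for glia (moody in all 3 replicates, and loco), 3 of 22 for muscle (tin, Msp300 and sls, all in 3 replicates), 1 of 10 for endoderm and gut (fkh), 1 of 10 for haemocytes (ush), 1 of 8 for fat body (Apoltp) and 2 of 17 for germline (bgcn and orb). For cell cycle genes the count was 2 of 20 (Cdk1 and CycB3). None of 14 epidermal barrier, 23 Osiris or 16 eggshell genes was bound, which allows shares of up to 23.2%, 14.8% and 20.6%. In replicate 2 alone 14.3% of the epidermal barrier genes were bound. Of 290 tRNA genes 19 were bound (6.55% against 10.5%, Fisher's exact test, adjusted p = 0.0875), and here replicate 2 stood apart with 13.1% against 1.38% and 3.79% in replicates 1 and 3.

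**Figure D3:**
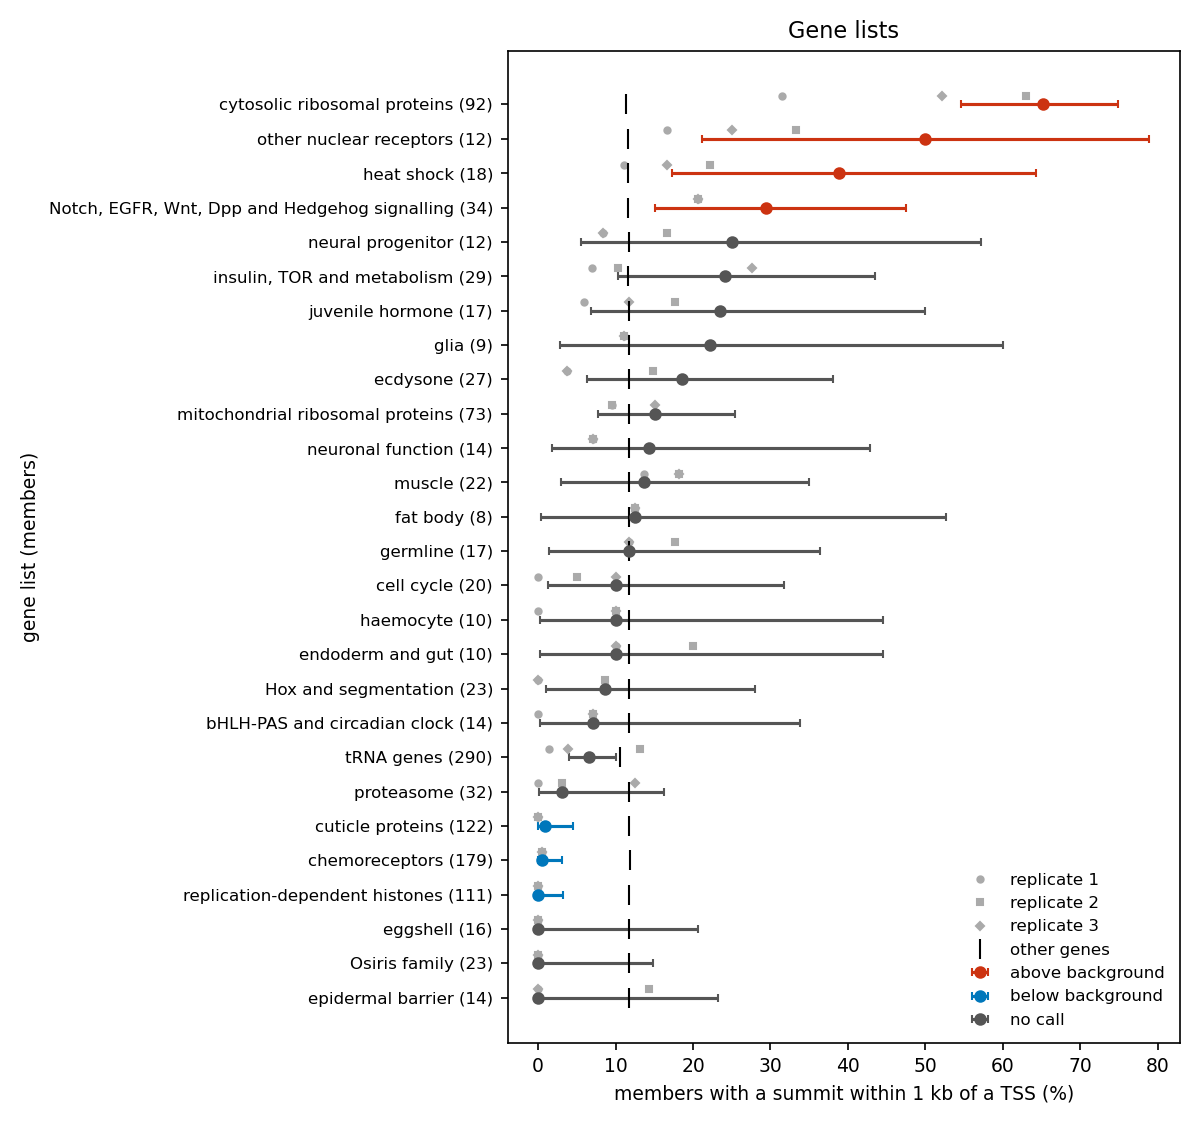
Share of each list's members with a summit within 1 kb of a TSS (percent, horizontal axis) for the 27 lists (vertical axis, members in parentheses), with exact 95% intervals, the share of other genes as a tick and the 3 replicates in grey. Cytosolic ribosomal protein genes stand at 65.2% and chemoreceptor genes at 0.559%.

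Peaks were spread unevenly over the arms relative to gene number. The X chromosome held 414 peaks where 373.5 were expected (ratio 1.11) and 3L held 1.08 times the expected number, while 3R held 527 where 581.9 were expected (ratio 0.906) and chromosome 4 held 4 (ratio 0.294). Arms 2L and 2R were at 0.987 and 0.989, and Y held 0. The permutation test over all arms gave p = 0.00097, and p = 0.00084, 0.0259 and 0.00017 in replicates 1, 2 and 3. Against an expectation from arm length in place of gene number, the ratio was 1.02 for X and 0.951 for 3R. The test over all arms gave permutation p = 1.0e-05, the smallest it can give. It also covers chromosome 4 and Y, with 2.97 and 0 peaks per Mb against 17.6 on X and 16.4 on 3R. A pass of the arm test is therefore not particular to X or 3R. Over the replicates the ratio to gene number was 0.898 ± 0.031 for 3R and 1.16 ± 0.124 for X (SD, n = 3). With the peaks put back that meet the IDR threshold and are missing from the thresholded lists, the ratio of 3R was 0.954 ± 0.043 (SD, n = 3). The test no longer passed with only the 678 peaks found in all 3 replicates (permutation p = 0.114) or the 920 found in both replicates 2 and 3 (permutation p = 0.0873).

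The words of juvenile hormone response elements were not more frequent at summits than 500 bp away. The E-box CACGTG was within 100 bp of 2.95% of summits and in 2.99% of flanking windows (ratio 0.986, adjusted p = 1, exact McNemar test), and the C-box CACGCG in 5.26% and 5.77% (ratio 0.912, adjusted p = 0.651). The replicate ratios were 1.16 ± 0.309 and 0.899 ± 0.312 (SD, n = 3). In the same exact test the words above the flank were those of the promoter elements DRE (TATCGATA, ratio 3.73, adjusted p = 4.61e-06) and M1BP (GGTCACAC, ratio 2.74), of Mef2 (ratio 1.78, adjusted p = 1.02e-07), of Ets factors (ratio 1.44, adjusted p = 0.0444) and GAGA (ratio 1.39, adjusted p = 0.0084), and control word 1, GTGCAC (ratio 2.10, adjusted p = 4.29e-09). GTGCAC kept its call in 13 of 14 alternatives and lost it within 50 bp of the summit (ratio 1.27, exact McNemar test, adjusted p = 0.402). The nuclear receptor word AAGGTCA (ratio 0.474), the repeat CACACACA (ratio 0.702) and the tgo core RCGTG (ratio 0.879) were below the flank. The ratio of AAGGTCA was 1.06 in replicate 1, 0.483 in replicate 2 and 0.591 in replicate 3, and it was 0.846 without replicate 2. The GAGA ratio was 2.32 in replicate 2 and 0.690 and 0.832 in replicates 1 and 3, and it was 0.787 without replicate 2. With only the peaks found in all 3 replicates or in any pair of them, the M1BP and nuclear receptor calls were lost, and those of DRE and Ets in each such set but the one without replicate 1. Their ratios kept their direction in these smaller sets, with 3.33 for M1BP, 2.5 for DRE, 1.54 for Ets and 0.692 for nuclear receptors in all 3 replicates. CACGCG was below its flank among the 1188 peaks with the higher signal (ratio 0.592, adjusted p = 0.0233) and without replicate 2 (ratio 0.482, adjusted p = 0.0077, both exact McNemar tests). Its control word CGACGC was also low in these 2 sets, at 0.707 and 0.660, without a call (exact McNemar test, adjusted p = 0.140 and 0.189). The low ratio is therefore not shown to be particular to CACGCG. The other words, for TACGTG, CATGTG, Zelda, Grainyhead, GATA, AP-1 and Ttk and the control words CGACGC and TGACTG, gave no call.

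The bases at summits differed from those beside them. Summit windows held 39.0% GC and flanks 42.5%, with 63.8% of summits below their flanks, and replicate 2 stood apart with 40.9% at summits against 36.2% and 37.0% in replicates 1 and 3. Against 11880 windows matched on GC and distance class to a TSS, in Fisher's exact test, CACGTG (ratio 1.48, adjusted p = 0.0113) and CACGCG (ratio 1.40, adjusted p = 0.0025) were above background, and so were the control words GTGCAC (ratio 2.12) and CGACGC (ratio 1.38, adjusted p = 0.0025). Matched on distance class alone, without GC, the windows gave ratios of 1.32 for CACGTG (adjusted p = 0.086) and 1.12 for CACGCG (adjusted p = 0.347, both Fisher's exact test), in a comparison added after the values were seen. Against the windows matched on both, the ratio of DRE was lower than against the flank, at 1.43 (Fisher's exact test, adjusted p = 0.035), and that of GAGA was higher, at 3.31 (Fisher's exact test, adjusted p = 4.14e-31). M1BP was at 2.34, Mef2 at 1.29 and Ets at 1.27 (Fisher's exact test, adjusted p = 0.0496 for Ets), all above background. Ets lost its call in 6 of 14 alternatives. These include windows matched on distance class alone (ratio 1.09, Fisher's exact test, adjusted p = 0.568), the list of 2133 peaks (1.15) and flanks 1 kb away (1.29). Split by location after the values were seen, the ratio of DRE to the flank was 5.78 in promoter peaks and 0.50 in the others (exact McNemar test, adjusted p = 1.81e-07 and 0.573). In promoter peaks Mef2 was at 2.26, GAGA at 2.19, Ets at 1.73 and M1BP at 3.67, all with a call. In the others they were at 1.29, 0.961, 1.32 and 4, without a call (exact McNemar test, adjusted p = 0.183, 0.955, 0.573 and 0.243). M1BP is rare there, at 0.643% against 0.161%. GTGCAC had a call in both, at 1.68 and 2.67. Against the windows matched on both, the tgo core (ratio 1.08) and the CA repeat (ratio 1.37) turned from below to above. The words for nuclear receptors (ratio 0.592) and Ttk (ratio 0.462) were below.

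**Figure D4:**
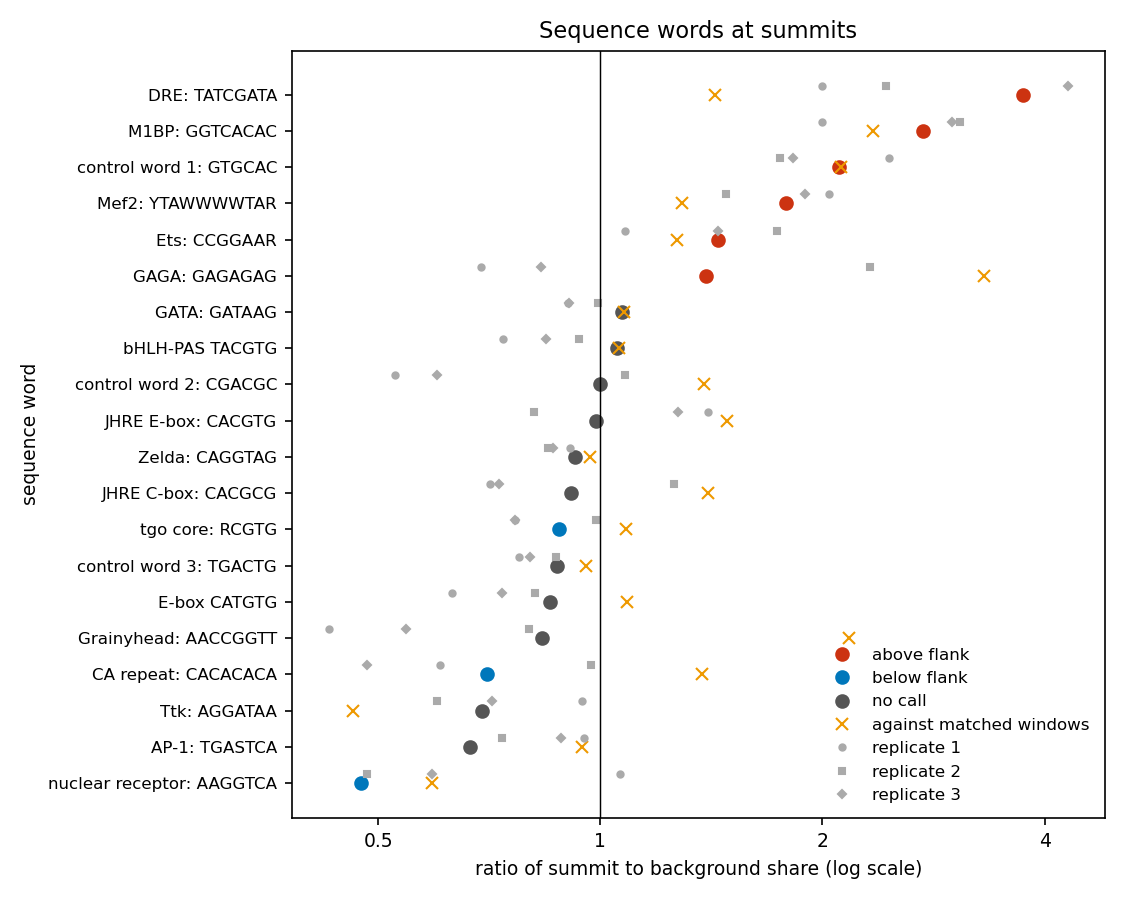
Ratio of the share of summits with a word to its share in the background (horizontal axis, log scale) for the 20 words (vertical axis), against the flank (filled points), against matched windows (crosses) and in the 3 replicates against the flank (grey). DRE stands at 3.73 and CACGTG at 0.986 against the flank, and CACGTG at 1.48 against matched windows.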

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

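The test of the peaks put back was fixed before its result was seen. Peaks that met the IDR threshold in a replicate's ranked list and are missing from its thresholded list numbered 45 in replicate 1, 85 in replicate 2 and 62 in replicate 3. The main comparisons do not use these peaks, apart from the ratio of 3R with them put back. Of those of replicate 1, 18 overlapped such peaks in both other replicates. They include the peak of rank 3 in the ranked list of replicate 1, on 2L at 480992 to 481186, 1416 bp from a TSS of cbt, and that of rank 11, on 3R at 11760962 to 11761128, 972 bp from a TSS of Lk6. Others had their nearest TSS at larp, tara, trx, Alh, Sirt6, Nuak, crp, Dph4 and RpL13A.

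The missing peaks were concentrated on 3R, with 21, 48 and 34 of them in replicates 1, 2 and 3, against 8, 17 and 18 on 2L. Their removal may account for part of the low number of peaks on 3R: with them put back, the mean ratio to the number expected from genes was 0.954 ± 0.043 (SD, n = 3), up from 0.898. The bound set beforehand for removal as the whole cause was 0.97. The mean stayed below it, which is the outcome set for removal not being the whole cause. It lies below by less than the spread between replicates, an allowance that the bound did not include. Removal as the whole cause is therefore not excluded with 3 replicates, and a true shortage on 3R remains open. The further input of the thresholded lists was not analysed here, and no biological explanation was tested.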

How the results depend on the processing

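The subset with an IDR score of 1000, the union of replicate lists with missing peaks put back, windows matched on TSS distance class alone and the heat shock split were chosen after seeing the data. Promoter share (36.1% to 57.9%) and replicate sharing (18.2% to 55.6%, between lists made from shared alignments) kept their direction and passed under each alternative run, 12 and 10 of them, and so did the cytosolic ribosomal list in 14 (30.4% to 71.7%). The mean of 1533 peaks was 766.3 in the higher-signal portion of each list and 1358 to 1743 with a replicate left out. The 7 lists with a call became 4 among the 1188 higher-signal peaks, 1 with peaks in all 3 replicates, 14 with nearest TSSs and 1 to 4 with a replicate left out, and the 9 words became 4 with peaks in all 3 replicates and 3 to 6 with a replicate left out. Apart from nearest TSSs, these sets hold fewer peaks by construction. Arms no longer passed with peaks in all 3 replicates (X ratio 1.201, permutation p = 0.114) and without replicate 1 (X ratio 1.13; range over the replicates left out 1.13 to 1.24), again with fewer peaks. With an expectation from arm length the X ratio was 1.02 and that of 3R 0.951. The arm test, which also covers the sparse chromosome 4 and Y, passed. Signalling fell to 2.94% with peaks in all 3 replicates and without replicate 3, below background and without a call. In each replicate's own list its share was 20.6%, above that of other genes. It was higher than in the main setting, at 50% within 5 kb (background 24.6%) and 52.9% with nearest TSSs. GAGA fell to 0.983 in the list of 2133 peaks, 0.917 with peaks in all 3 replicates and 0.787 and 0.921 without replicate 2 and 3 (1.22 without replicate 1). In each of these sets its call was lost, and no ratio below 1 passed the test. It was 3.31 against matched windows and 1.93 against flanks 1 kb away. With matched windows RCGTG (1.08) and CACACACA (1.37, and 1.24 when matched on distance class alone) reversed. CACGTG (1.48) and CACGCG (1.40), which had no call against the flank, were above background there. CGACGC, at a ratio of 1 to the flank, was at 1.38. Except where stated, the cause was not tested. The heat shock list lost its call in 9 of 14 alternatives and nuclear receptors in 10. Signalling lost it in 6 besides the 2 where its share fell below background. Read depth is unknown, and rare words and short lists limit what can be called.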

Other observations

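The tests of promoter and distal peaks apart, of windows matched on distance class alone, of control words against matched windows and of other broadly expressed genes were chosen only after the results they bear on were seen. Some long genes held several summits. The gene body of sbb (2R:18278198-18357296, 79.1 kb) held 12 conservative summits, those of CG1677 and ush held 9 each, kirre 8, and CHES-1-like, Tlk, atos and bun 7 each. ush, a cofactor of GATA factors, was counted once in the haemocyte list. These genes were picked by their count, and no test of clustering was run.

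Words chosen from the data recurred in peaks not used to choose them. Of 6583 words of 8 bases scored in 1188 odd-ranked peaks against matched windows, the 10 with the smallest p were tested in the 1188 even-ranked peaks, and 10 of 10 passed. Many of the 10 are shifted or reverse-complement copies of each other, such as CACTGTGC and CACAGTGG, so they are not 10 separate results. CACTGTGC was in 4.71% of even-ranked summit windows against 0.774% of matched windows (ratio 6.09, adjusted p = 2.72e-18, Fisher's exact test), CACAGTGG in 4.71% against 0.623% (ratio 7.57) and AGAGAGCG in 3.96% against 0.909% (ratio 4.35). These words may mark sequence at the summits beyond GC content, but they were not compared with the flank. Matched windows also differ from summits in place. The word GAGAGAG, which AGAGAGCG, GAGAGAAA and GAGAGAGC resemble, was at 3.31 against matched windows and 1.39 against the flank. Over the flank it was above 1 only in replicate 2 (2.32). Odd- and even-ranked peaks come from 1 list, so recurrence here is not replication. Whether gce itself binds the 10 words was not tested. The excess of control word GTGCAC was a candidate by-product of such words, and the test argues against the 5 chosen words holding CACTG as the whole cause. In the 2054 peaks without any of these 5 words, the ratio of GTGCAC to the flank was 1.82 (p = 3.26e-06, exact McNemar test). Peaks with variants of these words were not removed, so a longer sequence in variant form is not excluded.

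The lack of an excess of juvenile hormone response element words over the flank may come in part from base composition. Against windows matched on GC and distance class the larger ratio of the 2 words was 1.48, but this changes place as well as GC. Matched on distance class alone, CACGTG was already at 1.32 and CACGCG at 1.12. The steps between these ratios were not tested, so the parts of GC and of the place of the windows cannot be told apart. The control word CGACGC rose as well, from 1 against the flank to 1.38 against matched windows, and TGACTG gave no call against either. The log2 ratio of CACGCG exceeded that of CGACGC by 0.018 (interval -0.36 to 0.37). That of CACGTG was below that of its control word GTGCAC (difference -0.51, interval -1.01 to -0.10). GTGCAC was high against both backgrounds (2.10 and 2.12), so this difference cannot show whether the rise of CACGTG is particular to it. A rise particular to the hormone response words remains open. Summits placed away from the word may also contribute, since within 250 bp the ratio of CACGCG to flanks 1 kb away was 1.25 (exact McNemar test, adjusted p = 0.0084), but the control word CGACGC was at 1.23 there. No excess hidden by promoter peaks was seen in the 1245 peaks over 500 bp from a TSS. There the ratio to the flank was 0.906 for CACGTG and 0.694 for CACGCG (exact McNemar test, adjusted p = 0.939 and 0.183). CACGTG is rare there, at 2.33% against 2.57%, and the background is again the flank. The control word CGACGC was at 0.657 there (exact McNemar test, adjusted p = 0.147), near the ratio of CACGCG. The flank comparison may thus lower such words, and a hidden excess is not excluded. In the 1131 promoter peaks CACGTG was at 1.71 (exact McNemar test, adjusted p = 0.088).

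The high share of bound cytosolic ribosomal protein genes was set against 3 technical explanations. The number of TSSs per gene does not account for it, since none of the draws of 10000 matched lists came as high (permutation p = 0.00020, the smallest the draws can give). Neighbouring genes do not account for it, as 16 of the 34 members with no other protein-coding TSS within 1 kb were bound (47.1% against 7.70%, Fisher's exact test, p = 1.03e-09). Calling at any broadly expressed promoter is argued against by the mitochondrial ribosomal and proteasome lists, whose upper limits reach 25.4% and lie below the lower limit of 54.6%. Very high transcription, which can raise ChIP signal with any antibody, was not tested because the control was not analysed here, and it stays open beside occupancy by gce.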
